A study of Mus musculus and Rattus norvegicus with 79 samples.

How the data were processed

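Liver RNA of 27 C57BL/6 mice (polyA libraries) and of 36 Nr3c1fl/fl mice injected with a virus for GFP or CRE (total RNA depleted of ribosomal RNA), and RNA of 12 rat hepatocyte cultures (polyA libraries), was sequenced, and GR was immunoprecipitated from liver chromatin at ZT10. About 5 mg of liver entered each RNA extraction and 1000 ng of RNA each library, per the labels. The hepatocytes were plated with dexamethasone and insulin and depleted of serum for 4 h before stimulation, per the labels' protocols, so the control cells had met both hormones earlier. The ethanol libraries were taken as the vehicle control.

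The authors deposited a table of raw counts per RefSeq transcript for each of the 3 RNA experiments, with 1 column per library. STAR, HOMER and DESeq2 and the builds mm10 (mouse) and rn5 (rat) are named, without versions or roles, per the submitters' processing notes. Isoforms of one gene stand in separate rows of the deposited count tables and count the same reads. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping or antisense gene, and near-identical family members such as Mup, Cyp2 and Serpina1 genes, cannot be told apart with certainty. Of counts from 1 to 10 per library, 75.7% to 85.1% are even in the deposited mouse tables and 37.7% to 41.4% in the rat table. The authors' 3 peak lists hold only chromosome, start and end, with no score or height, and whether starts count from 0 or 1 is not given in the sources used here. They were read as counting from 0, so printed starts are 1 higher than deposited. Per the file names these are peaks found in both replicates, peaks called against input and peaks called against chromatin of CRE livers, and thresholds or pooling are not given in the sources used here.

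Mouse transcripts were matched by accession to the gene table of assembly GRCm38.p6, whose coordinates are those of mm10: 40219 of 40458 rows matched, giving 24790 genes, of which 7581 had several rows. The row with the highest total over both mouse tables stood for a gene. Unmatched rows stayed out of library sizes and tests and held 0.308% to 2.24% of the counts of C57BL/6 libraries and 2.43% to 28.6% of those of Nr3c1fl/fl libraries. The row NR_046233 among them held 0.096% to 2.05% and 2.23% to 28.5%. The rat table has 18269 rows, of which 1573 repeat another row and 2565 are all 0, leaving 14132 distinct rows with the all-0 row counted once, and no gene names were paired with its identifiers.

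Counts were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with the groups, and the quasi-likelihood F-test, 1 fit per experiment so that all groups share an estimate of the spread. Benjamini-Hochberg adjusted p-values under 0.05 counted as past the threshold, and adjusted p-values of single genes are edgeR's unless DESeq2 is named. Log2 fold changes carry standard errors computed as the size of the change over the square root of F. After filtering, 14744, 15712 and 10843 genes or transcripts were tested. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, over 25 lists per comparison, again with an estimated correlation and with fry, and list p-values are camera's. CPM are counts over the TMM-scaled tested total in M. Peaks were compared with bedtools 2.31.1, and logistic models were fitted with statsmodels 0.14.6. A peak counted as near a gene within 25 kb of the gene interval, because the gene table used here gives no strand and so no start site. DESeq2 1.42.0 was an alternative. Permutation tests of single values were two-sided.

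The comparisons, the main tests, the gene lists, most other settings and the rule for named genes were fixed before the data were examined. Named are 22 fixed genes and up to 4 genes of each fixed list with the smallest p. Named too are, in each comparison, up to 6 genes with the largest change up and 6 down among those past the threshold with at least 5 CPM on average and no overlap between the groups' libraries. Interactions and F-tests were ranked by adjusted p, and means over times needed the same direction at every time. The fixed lists are 17 of pathways and 11 of cell types and RNA quality. The former are GR targets, gluconeogenesis, glycolysis and glycogen, lipid synthesis, cholesterol synthesis, fatty acid oxidation, insulin signalling, clock, unfolded protein response, amino acids and urea cycle, bile acids, male-biased growth hormone genes, acute phase, immediate early, heat shock, ribosome biogenesis and xenobiotic metabolism. The latter are markers of hepatocytes, Kupffer, endothelial, stellate, bile duct, lymphoid, neutrophil, red blood, pancreatic and fat cells and of mitochondrial transcripts. Lists with fewer than 3 measured members were not tested. Angptl8 in fed CRE livers is given outside this rule, beside its value in GFP livers. Results of some single genes that the rule names are not reported here. Some genes stand on several lists, such as Tat, Pck1 and Lpin1.

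The tests were checked on simulated counts drawn from the real means and library sizes, with 200 genes changed. The changed genes were drawn only from those with higher mean counts, so recovery among genes with few counts was not measured. At a change of 1 log2 unit edgeR recovered 90% of 100 changed genes for fed against unfed at ZT14 (14571 genes in the fit), 99% for its mean over times (14582 genes) and 77% for its difference among hours (14569 genes). For CRE against GFP it recovered 86% at ZT13 (15537 genes), 100% for the mean over times (15563 genes) and 62% for the difference among times (15548 genes), and for dexamethasone 100% (10772 genes). At 2 log2 units the shares were 100%, 100%, 97%, 100%, 100%, 93% and 100%. Genes that had not been changed made up 2.5% (CRE among times) to 6.1% (CRE at ZT13 and dexamethasone) of edgeR's calls. Total counts in tested rows ranged from 13.6 to 52.7 M in C57BL/6 libraries, 13.87 to 40.38 M in Nr3c1fl/fl libraries and 9.44 to 23.35 M in hepatocytes. Hence 3 counts, the limit that a count of 0 allows, equal 0.0569 to 0.221, 0.0743 to 0.216 and 0.129 to 0.318 CPM. Such floors cover counting error only. Replicates are separate samples of a group per the labels, which do not say whether hepatocyte cultures came from separate rats, and p-values measure only the spread between these samples. No pair of replicates agreed within counting noise: their spread was 3.04 to 12.42 times that of Poisson counts in C57BL/6 livers, 3.65 to 14.53 times in Nr3c1fl/fl livers and 1.29 to 2.91 times in hepatocytes. Most low mouse counts are even, as when both reads of a pair are counted. If so, which was not tested, the mouse ratios are too high and the mouse floors too low. The mouse values are therefore not comparable with those of the rat cells.

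The other settings fixed at that stage were DESeq2, RLE size factors in edgeR, no filter on low counts, the replicate number as a block, only the groups compared in the fit, each library left out in turn, other set tests, and other windows, overlaps and lists for peaks. Chosen after seeing the data were the share of NR_046233 as a covariate, leaving out 6 libraries with over 20% of counts there, leaving out 2 C57BL/6 libraries with transcripts of other tissues, halved counts, leave-one-out for the sets, sets made without those 2 C57BL/6 libraries, gene length in the peak model and a background of genes of at least 5 CPM.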

Results

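Gene expression was measured by RNA sequencing in mouse liver and in rat hepatocytes in primary culture, and binding sites of the glucocorticoid receptor (GR, the product of Nr3c1) were mapped in mouse liver by chromatin immunoprecipitation. Time is given as Zeitgeber time (ZT), the hours since lights on in a cycle of 12 h light and 12 h dark, and the mice were trained to eat at night. The first experiment holds 27 polyA libraries from C57BL/6 livers in 9 groups of 3, unfed at ZT10 and both fed and unfed at ZT13, ZT14, ZT18 and ZT22. The second holds 36 libraries depleted of ribosomal RNA from Nr3c1fl/fl livers in 12 groups of 3, taken 10 days after injection of an adeno-associated virus that carries GFP (control) or CRE (the recombinase that excises the floxed part of Nr3c1) behind the hepatocyte promoter tbg. These mice were unfed at ZT10 and ZT12 and fed at ZT13, ZT14, ZT18 and ZT22. The third holds 12 polyA libraries from Sprague Dawley rat hepatocytes in 4 groups of 3. These are an ethanol control, dexamethasone (a synthetic glucocorticoid, 500 nM for 2.5 h), insulin (for 2 h) and both. The total count per library was 23.87 to 91.77 M (median 43.6 M) in C57BL/6 livers, 34.64 to 78.76 M (median 53.4 M) in Nr3c1fl/fl livers and 9.8 to 24.22 M (median 17.6 M) in hepatocytes. The plot of genes past the threshold summarises the pairwise comparisons.

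**Figure D1:**
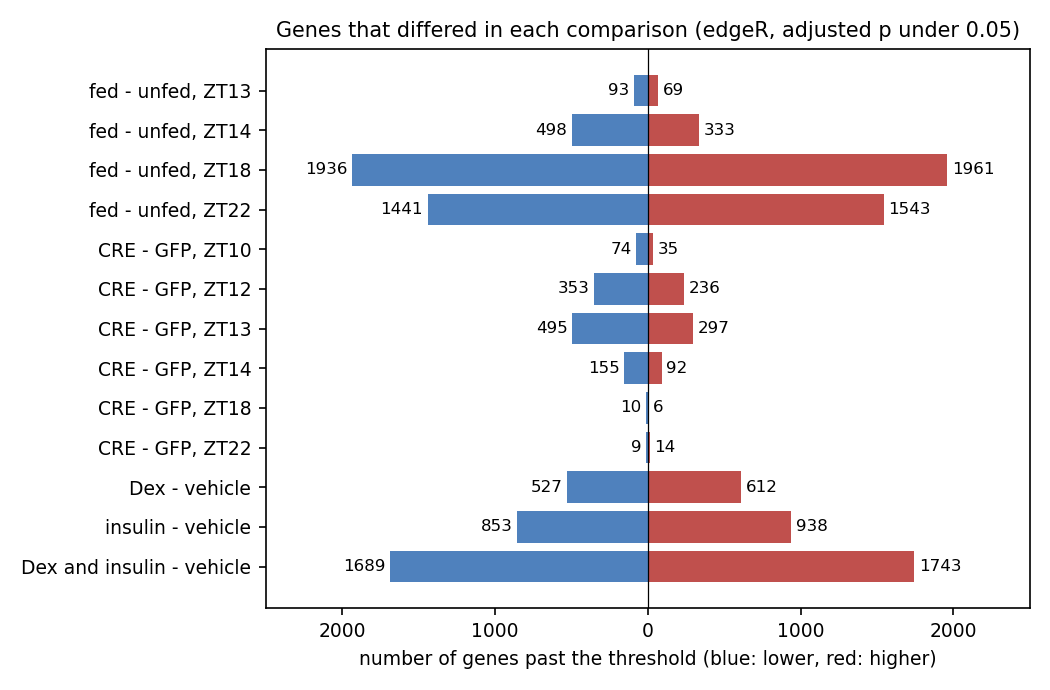
Number of genes past an adjusted p of 0.05 (x axis, edgeR) in each comparison (y axis), with genes lower in the group named first in blue and genes higher in it in red. In C57BL/6 livers the count was 162 at ZT13 and 3897 at ZT18, and between CRE and GFP livers it was 792 at ZT13 and 16 at ZT18.

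The first comparison asks which liver transcripts follow food at a given hour of the night. Averaged over ZT13, ZT14, ZT18 and ZT22, fed C57BL/6 livers held more mRNA of lipid synthesis genes and less Igfbp1 and Pck1 mRNA than unfed livers of the same hour. Fasn, the fatty acid synthase, rose by 2.15 ± 0.10 (log2 fold change ± SE, adjusted p = 9.87e-14, 12 libraries a side). At ZT22 alone, where it rose by 2.94, it was at 152 ± 41.2 CPM unfed and 1170 ± 292 CPM fed (library-normalised read counts, mean ± SD, n = 3). Srebf1, a transcription factor of lipid synthesis, rose by 1.78 ± 0.11. Igfbp1, a gene repressed by insulin, fell by 2.81 ± 0.20, and Pck1, the phosphoenolpyruvate carboxykinase of glucose production, fell by 1.40 ± 0.14 (adjusted p = 3.36e-08). Nr3c1 itself was at 0.06 ± 0.05 (adjusted p = 0.323). In all, 2579 genes rose and 2636 fell among 14744 tested.

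Of 25 fixed lists tested in the same average 11 passed camera with a preset correlation and 1 with an estimated correlation. All 20 cholesterol synthesis genes rose, with Mvd at 2.24 ± 0.11 and Fdps at 1.80 ± 0.10, and 20 passed adjusted over the list alone (camera adjusted p = 1.19e-21; adjusted p = 0.0562 with an estimated correlation). Of 20 genes of fatty acid and triglyceride synthesis 16 rose, among them Elovl6 (1.76 ± 0.06), Acly (1.40 ± 0.07) and Pnpla3 (3.19 ± 0.26), 1 fell and 18 passed adjusted over the list alone. This was the list whose call held both ways (adjusted p = 3.89e-12, and adjusted p = 0.00669 with an estimated correlation). Of 22 genes of the unfolded protein response 17 rose and 3 fell, with Sdf2l1 at 1.71 ± 0.15 and Manf at 1.23 ± 0.11, and 20 passed adjusted over the list alone (adjusted p = 7.85e-08; adjusted p = 0.111 with an estimated correlation). Cytosolic heat shock genes rose in 9 of 12 cases, such as Hsp90aa1 (1.01 ± 0.10) and Stip1 (0.66 ± 0.09), and 9 passed adjusted over the list alone (adjusted p = 4.03e-05; adjusted p = 0.226 with an estimated correlation). Ribosome biogenesis genes rose in 8 and fell in 2 of 20 cases, and 11 passed adjusted over the list alone (adjusted p = 0.0291; adjusted p = 0.604 with an estimated correlation).

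Lower in fed livers were 17 of 21 genes of fatty acid oxidation and ketogenesis, with none higher and 17 past adjusted over the list alone (adjusted p = 2.03e-10; adjusted p = 0.111 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell by 0.89 ± 0.06, the fasting hormone gene Fgf21 fell by 2.76 ± 0.30, and Angptl4 fell by 1.66 ± 0.14. Of 25 textbook GR targets 19 fell and 2 rose, and 22 passed adjusted over the list alone (adjusted p = 4.46e-07; adjusted p = 0.167 with an estimated correlation). The metallothionein Mt2 fell by 2.84 ± 0.26, Fkbp5 fell by 0.90 ± 0.13 and Klf9 fell by 0.78 ± 0.07, while Tsc22d3 was at 0.05 ± 0.12 (adjusted p = 0.777), and at -0.05 without replicate 2 of the fed livers at ZT22. Gluconeogenesis genes fell in 11 and rose in 1 of 16 cases (13 adjusted over the list alone; adjusted p = 0.00052; adjusted p = 0.249 with an estimated correlation). Genes of insulin signalling fell in 7 and rose in 1 of 14 cases (9 adjusted over the list alone; adjusted p = 0.000827; adjusted p = 0.103 with an estimated correlation), with Irs2 at -1.22 ± 0.15 and Insr at -0.38 ± 0.04. Amino acid breakdown and urea cycle genes fell in 9 of 20 cases (9 adjusted over the list alone; adjusted p = 0.00739; adjusted p = 0.604 with an estimated correlation).

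Beside these groups, all 10 endothelial cell markers were lower in fed livers (10 adjusted over the list alone; adjusted p = 4.03e-05; adjusted p = 0.103 with an estimated correlation), with Kdr at -0.44 ± 0.07 and Stab1 at -0.35 ± 0.06. No Kupffer cell marker of 11 passed, and of the hepatocyte markers 2 rose and 1 fell among 9. Glycolysis and glycogen genes rose in 8 and fell in 2 of 20 cases (11 adjusted over the list alone; adjusted p = 0.0863), with the pyruvate kinase Pklr at 0.99 ± 0.08. Clock genes rose in 3 and fell in 8 of 18 cases (13 adjusted over the list alone; adjusted p = 0.132), with Per2 at 0.67 ± 0.08 and Nr1d2 at -1.03 ± 0.08. Of 12 immediate early genes 1 rose and 5 fell (6 adjusted over the list alone; adjusted p = 0.0863), with Junb at -0.80 ± 0.10.

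**Figure D2:**
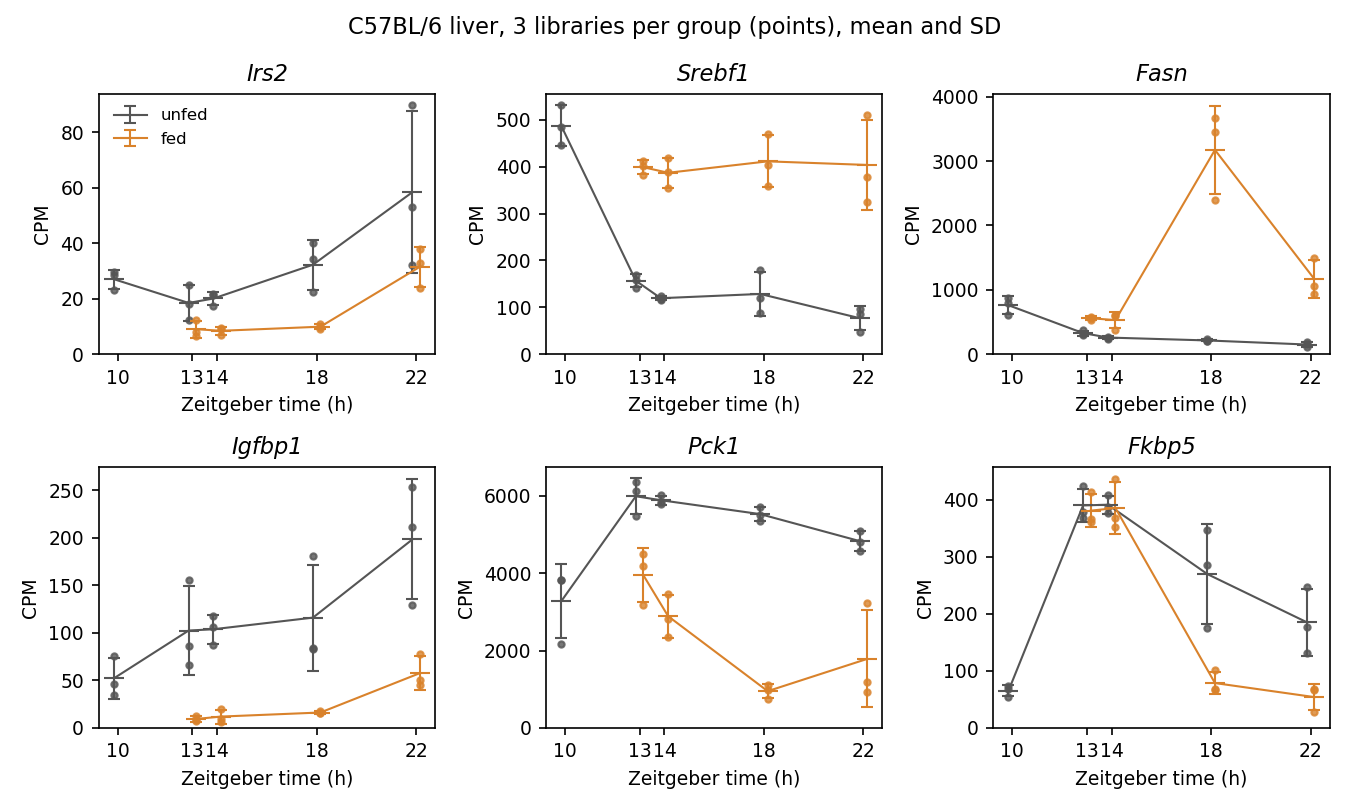
Expression in C57BL/6 livers of Irs2, Srebf1, Fasn, Igfbp1, Pck1 and Fkbp5 in CPM (y axis) by Zeitgeber time in hours (x axis), each point a library, with mean and SD bars per group of 3 for fed and unfed mice. Mean Igfbp1 in fed livers was 9.31 CPM at ZT13 against 102 CPM in unfed livers.

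The same question was then asked at each hour. At ZT13, 69 genes rose and 93 fell. Angptl8, a feeding-induced regulator of lipoprotein lipase, rose by 2.60 ± 0.46 (adjusted p = 0.00353) and Srebf1 by 1.35 ± 0.21 (adjusted p = 0.00139), whereas Igfbp1 fell by 3.45 ± 0.41 and Depp1 fell by 2.66 ± 0.44. Of the heat shock genes 4 of 12 rose, with 10 past adjusted over the list alone. The count at ZT13 moved when a library was left out, which also leaves fewer libraries in the fit. It was 434 without unfed replicate 1, 76 and 72 without unfed replicates 2 and 3, and 40 and 85 without fed replicates 2 and 3. With these 2 groups alone in the fit it was 95, and DESeq2 called 350.

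At ZT14, 333 genes rose and 498 fell. Igfbp1 fell by 3.14 ± 0.41, Pck1 fell by 1.03 ± 0.28 (adjusted p = 0.0308) and Srebf1 rose by 1.69 ± 0.21. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 1.95 ± 0.32 while its repressor Nr0b2 fell by 1.69 ± 0.35. Of the unfolded protein response genes 9 rose and 2 fell among 22 (15 adjusted over the list alone). The mean log2 level of the Kupffer cell markers was 3.65 to 4.28 in fed and 3.45 to 3.48 in unfed libraries. That of the bile duct markers was 3.26 in fed replicate 1, against 1.20 and 1.51 in fed replicates 2 and 3 and 1.64 to 1.71 in unfed libraries. The stellate cell marker Acta2 was called at 5.20 ± 1.17 (adjusted p = 0.00843), but at 1.64 without fed replicate 1 (adjusted p = 0.389) and at 4.78 without unfed replicate 3 (adjusted p = 0.0534). Without unfed replicate 1, 2 or 3 the ZT14 count was 389, 389 and 458, and without fed replicate 1 or 3 it was 409 and 501. Pck1 was not past the threshold in any of these fits (adjusted p = 0.0855 to 0.163). With the ZT14 groups alone in the fit the count was 1318, and it was 444 without fed replicate 1 and unfed ZT18 replicate 3, which held transcripts of other tissues (Pck1 at -0.88, adjusted p = 0.174).

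At ZT18, 1961 genes rose and 1936 fell, and at ZT22, 1543 rose and 1441 fell. All 20 cholesterol synthesis genes rose at each of these hours. At ZT18 Fasn rose by 3.88 ± 0.22 (adjusted p = 3.1e-12) and Pnpla3 by 5.58 ± 0.52. Hspa5, the main chaperone of the endoplasmic reticulum, rose by 1.67 ± 0.20, and Mt2, Mt1, Igfbp1 and Pck1 were at -4.85 ± 0.58, -4.27 ± 0.47, -2.85 ± 0.39 and -2.54 ± 0.30. Fkbp5 fell by 1.78 ± 0.26 at ZT18, where all 10 endothelial markers were lower too. At ZT22 Thrsp rose by 4.24 ± 0.33, Fdps by 3.39 ± 0.22, Fasn by 2.94 ± 0.21, Srebf1 by 2.39 ± 0.22 and Ppp1r3b, which targets a phosphatase to glycogen, by 1.27 ± 0.14, and Pck1 fell by 1.44 ± 0.29. The ZT18 count was 2530 without fed replicate 1, and the ZT22 count was 1752 with its 2 groups alone in the fit.

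Whether the response to food itself differed among the 4 hours was tested as an interaction. It did for 1194 genes (1871 by DESeq2), led by the lipid synthesis genes Elovl6 (adjusted p = 4.49e-11), Acly (adjusted p = 8.87e-11), Acss2 (adjusted p = 1.54e-10) and the cholesterol synthesis gene Dhcr7 (adjusted p = 2.9e-10). Elovl6 was at 176 ± 21 CPM fed and 132 ± 7.86 CPM unfed at ZT13, and at 492 ± 32.5 and 51.7 ± 5.3 CPM at ZT18. Of the cholesterol synthesis genes 19 of 20 passed this test and of the lipid synthesis genes 12 of 20, with 20 and 16 adjusted over the list alone. For Igfbp1 (adjusted p = 0.127) the test found no difference among the hours.

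Time without food was examined over the unfed livers at ZT10, ZT13, ZT14, ZT18 and ZT22, in which hour and hours since the last meal change together. Expression differed for 6260 genes, led by the clock gene Arntl (adjusted p = 3.51e-15), Clpx and the clock output gene Dbp. Mean Arntl was 1.15 ± 0.21 CPM at ZT10 and 51 ± 1.06 CPM at ZT22, and Dbp was 284 ± 44.9 and 6.57 ± 2.26 CPM (n = 3 each). Of the clock genes 17 of 18 changed, of the heat shock genes 12 of 12 and of the lipid synthesis genes 19 of 20, with 17, 12 and 19 adjusted over the list alone. Fkbp5 was at 64.9 ± 9.72 CPM at ZT10 and 392 ± 15.9 CPM at ZT14 (adjusted p = 2.4e-07 over the 5 times).

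The second experiment asks which liver transcripts depend on GR in hepatocytes. The targeted gene came first: Nr3c1 was lower in CRE than in GFP livers by 0.63 ± 0.06 (log2, mean of the 6 times, adjusted p = 1.85e-09, 18 libraries a side). At each time every CRE library lay below every GFP library, an outcome that chance gives in 10% of arrangements of 3 against 3 at 1 time when either order counts. At ZT12 Nr3c1 was at 114 ± 11.9 CPM in CRE and 214 ± 17.6 CPM in GFP livers. By time its log2 fold change was -0.75 ± 0.14 at ZT10, -0.91 ± 0.14 at ZT12, -0.48 ± 0.14 at ZT13, -0.73 ± 0.14 at ZT14, -0.42 ± 0.14 at ZT18 and -0.52 ± 0.14 at ZT22, with those at ZT18 and ZT22 not past the threshold (adjusted p = 0.342 and 0.141). The count covers the whole transcript and all cells of the liver, so it does not give the share of hepatocytes that lost the receptor. Nr3c1 at ZT13 (adjusted p = 0.0405) was not past the threshold without GFP replicate 1, 2 or 3 or CRE replicate 1 or 3 (adjusted p = 0.0593 to 0.219), with the ZT13 groups alone (adjusted p = 0.278), with the NR_046233 share as a covariate (adjusted p = 0.0631) or without 6 libraries with over 20% of counts in that row (adjusted p = 0.0508), nor at ZT14 without GFP replicate 1 (adjusted p = 0.0787).

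Averaged over the 6 times, 1245 genes were higher and 1044 lower in CRE livers among 15712 tested. Of 24 measured GR targets 21 were lower and none higher (22 adjusted over the list alone), and this call held both ways (camera adjusted p = 1.02e-23; adjusted p = 0.000492 with an estimated correlation). Fkbp5 fell by 1.77 ± 0.13, Lpin1, a phosphatidate phosphatase and coactivator, fell by 2.53 ± 0.10, Zbtb16 fell by 2.17 ± 0.13, and Tsc22d3 fell by 1.00 ± 0.12. Pfkfb2 fell by 0.65 ± 0.05. Of the glycolysis and glycogen genes 6 were lower and 1 higher among 20 (9 adjusted over the list alone; adjusted p = 0.00412; adjusted p = 0.358 with an estimated correlation). Of 16 gluconeogenesis genes 7 were lower and 1 higher (11 adjusted over the list alone; adjusted p = 0.00435; adjusted p = 0.481 with an estimated correlation), with Pck1 at -0.79 ± 0.10 and Tat, a tyrosine aminotransferase, at -0.59 ± 0.10. Amino acid breakdown and urea cycle genes were lower in 11 and higher in 2 of 20 cases (16 adjusted over the list alone; adjusted p = 1.61e-09; adjusted p = 0.33 with an estimated correlation), with Arg1 at -0.76 ± 0.06, Asl at -0.72 ± 0.08 and Cps1 at -0.55 ± 0.06.

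Fatty acid oxidation genes were higher in CRE livers in 10 and lower in 1 of 21 cases (13 adjusted over the list alone; adjusted p = 4.6e-06; adjusted p = 0.358 with an estimated correlation), with Plin2 at 0.66 ± 0.08 and Bdh1 at 0.60 ± 0.07. Lipid synthesis genes were higher in 7 and lower in 3 of 20 cases (15 adjusted over the list alone; adjusted p = 0.0345; adjusted p = 0.597 with an estimated correlation), with Elovl5 at 0.67 ± 0.09 and Fads2 at 0.51 ± 0.08. Cholesterol synthesis genes went both ways, 3 higher and 3 lower of 20 (8 adjusted over the list alone; adjusted p = 0.775). Of 9 hepatocyte markers 4 were lower and 1 higher (5 adjusted over the list alone, camera adjusted p = 0.0544, and adjusted p = 0.358 with an estimated correlation). No list of cell type markers passed in this average, and Kupffer cells had the next lowest value (camera adjusted p = 0.0992). At single times the mean marker level of the 3 CRE libraries lay wholly above or below that of the 3 GFP libraries in 9 of 48 cases (8 cell type lists at 6 times), where chance gives 10%. Of these 9, 4 were hepatocyte markers, each time lower in CRE livers (ZT10, ZT12, ZT14 and ZT18). The row NR_046233, which the gene annotation used here does not name, held 2.23% to 28.5% of all counts in these libraries and over 20% in 6 of them; without those 6, which left no GFP library at ZT10 and 1 at ZT12, 1372 genes passed in the average of the other times.

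**Figure D3:**
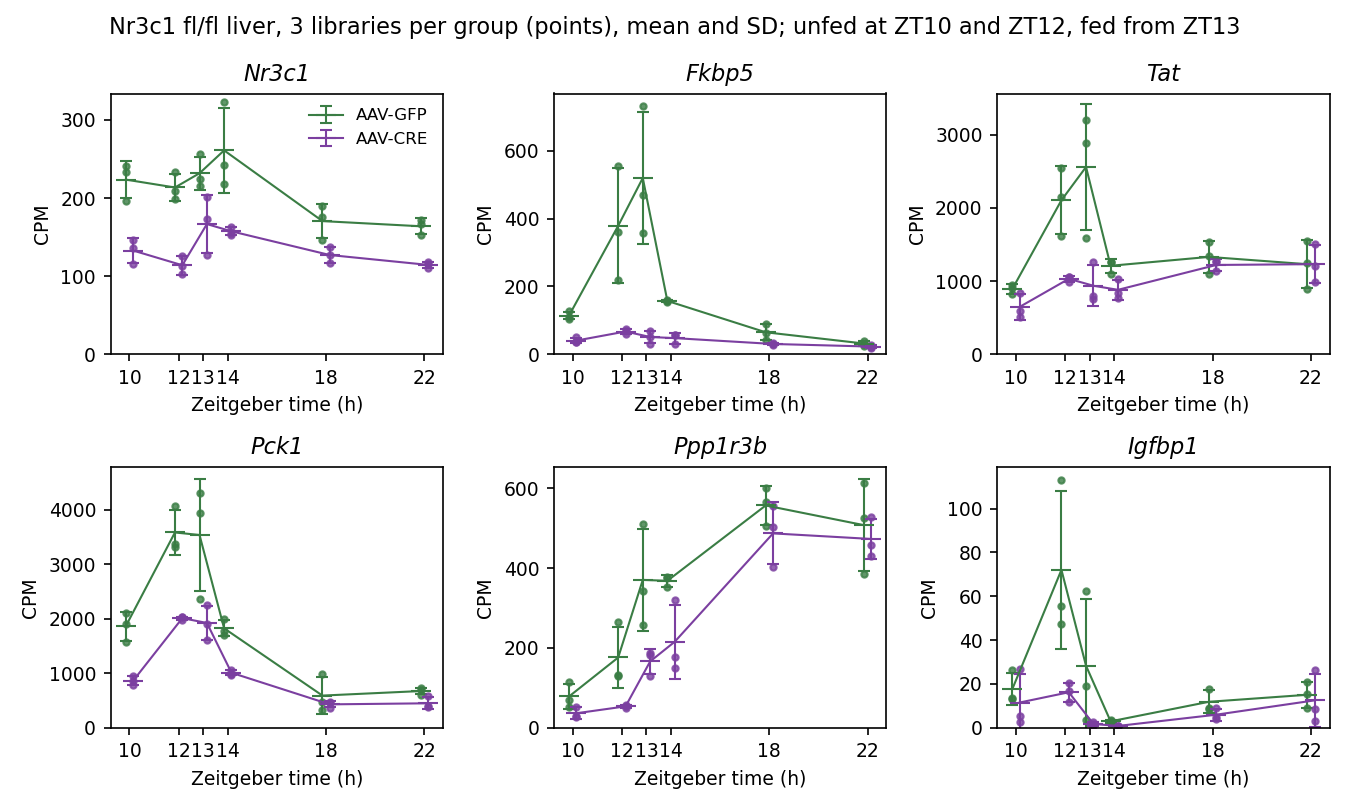
Expression of Nr3c1, Fkbp5, Tat, Pck1, Ppp1r3b and Igfbp1 in CPM (y axis) in Nr3c1fl/fl livers by Zeitgeber time in hours (x axis), each point a library, with mean and SD bars per group of 3 for GFP and CRE. Mean Fkbp5 was 519 CPM in GFP and 51.1 CPM in CRE livers at ZT13.

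The count differed by hour. At ZT10, 35 genes were higher and 74 lower in CRE livers, with Zbtb16 at -3.14 ± 0.34, Lpin1 at -2.42 ± 0.24 and Fkbp5 at -1.50 ± 0.31. At ZT12, 236 were higher and 353 lower. Ppp1r3b fell by 1.71 ± 0.31, the fructose-2,6-bisphosphate enzyme gene Pfkfb3 fell by 2.12 ± 0.24 and Lpin1 fell by 4.09 ± 0.26, with Fkbp5 at -2.49 ± 0.31, Foxo1 at -0.87 ± 0.11 and Nr1d1 at 1.32 ± 0.27. The NR_046233 share was 21.9% ± 8.75 in unfed GFP and 11.7% ± 9.84 in unfed CRE livers (mean ± SD, ZT10 and ZT12 together). With that share as a covariate the count was 65 at ZT10 and 229 at ZT12. Without the 6 libraries above 20% the GFP side at ZT12 was replicate 3 alone, assumed to vary like the other groups, and the count was 105, with Ppp1r3b at -1.28 (adjusted p = 0.0928) and Nr1d1 at 1.19 (adjusted p = 0.411). DESeq2 called 197 genes at ZT10. The mean log2 level of the hepatocyte markers was 11.27 to 11.28 in CRE and 11.34 to 11.42 in GFP libraries at ZT10, with 0 of 9 past adjusted over the list alone, and 11.39 to 11.48 and 11.56 to 11.70 at ZT12, with 2 lower (3 adjusted over the list alone). The endothelial markers at ZT10 were at 5.74 to 5.83 and 5.55 to 5.68, with 0 of 10 past adjusted over the list alone. At ZT12 the mean log2 level of the bile duct markers was 0.99 to 1.24 in CRE and 0.42 to 0.78 in GFP libraries, with 1 of 7 markers higher (1 adjusted over the list alone), and the lymphoid markers too were apart, at 0.21 to 0.33 and -0.02 to 0.15. Without GFP replicate 1, 2 or 3 or CRE replicate 2 the ZT10 count was 60, 69, 62 and 43, and Fkbp5 was not past the threshold without GFP replicate 3 or CRE replicate 2 or 3 (adjusted p = 0.0547, 0.0932 and 0.065). Without GFP replicate 2 or CRE replicate 1, 2 or 3 the ZT12 count was 267, 339, 318 and 389.

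At ZT13, 297 genes were higher and 495 lower in CRE livers. Of the GR targets 19 of 24 were lower (23 adjusted over the list alone), and of the amino acid and urea cycle genes 10 of 20 (13 adjusted over the list alone). Lpin1 fell by 4.22 ± 0.26, Igfbp1 fell by 4.00 ± 0.82 and Fkbp5 fell by 3.35 ± 0.32 (adjusted p = 4.45e-08). Ppp1r3c fell by 2.51 ± 0.46, Tat fell by 1.45 ± 0.24 and Foxo1 fell by 1.15 ± 0.11. Fasn was called at 0.90 ± 0.27 (adjusted p = 0.0494), and the call ended without each of the 6 libraries in turn (adjusted p = 0.0584 to 0.213), without a filter on low counts (adjusted p = 0.0539), with the replicate block (adjusted p = 0.0596), with the ZT13 groups alone (adjusted p = 0.078) and without the 6 libraries above 20% NR_046233 (adjusted p = 0.0676). The ZT13 count was 375, 406 and 1343 without GFP replicate 1, 2 and 3, and 55 with these 2 groups alone in the fit, where Igfbp1, Tat and Ppp1r3c had adjusted p = 0.129, 0.108 and 0.11. Igfbp1 also failed without GFP replicate 1 (adjusted p = 0.0584).

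At ZT14, 92 genes were higher and 155 lower, with Eif4ebp3 at -3.29 ± 0.31, Lpin1 at -3.04 ± 0.25 and Fkbp5 at -1.72 ± 0.31; the count was 79 without GFP replicate 1, 74 and 78 without CRE replicates 2 and 3, and 417 by DESeq2. At this hour Kupffer cell markers had a median of -0.63, with 1 of 11 lower and 8 past adjusted over the list alone, and their mean log2 level was 3.64 to 3.85 in CRE and 4.37 to 4.57 in GFP libraries. Without 1 of the 6 libraries 2 to 7 of the 11 passed adjusted over the list alone. Hepatocyte markers were at 11.20 to 11.34 and 11.37 to 11.54, and at ZT18 at 11.35 to 11.42 and 11.43 to 11.59. At ZT18, 6 were higher and 10 lower, and at ZT22, 14 and 9. Of 5 red blood cell markers 3 passed at ZT18 adjusted over the list alone (median 2.47), but 0 without GFP replicate 1 or 3 or CRE replicate 1 or 3. Of 11 stellate cell markers 4 did at ZT22 (median -0.58), but 0 without GFP replicate 3 or CRE replicate 2 and 1 without CRE replicate 1. That GFP replicate 3 had a mean log2 level of 4.89 against 4.05 and 4.09 in the other 2 GFP and 3.76 to 4.15 in the CRE libraries, and it held Col3a1 at 180 CPM. The late counts moved several fold with the tool and the fit: DESeq2 called 80 and 92 genes, and with the 2 groups alone in the fit edgeR called 65 and 0. The ZT22 count was 10 without the 6 libraries above 20% NR_046233, none of them taken at ZT22. Eif4ebp3 fell by 3.44 ± 0.32 at ZT18. Cyp17a1, a steroid hydroxylase, was called at -2.74 ± 0.56 at ZT18 (adjusted p = 0.0384) and -2.78 ± 0.55 at ZT22 (adjusted p = 0.0254), whereas Lpin1 was at -0.96 ± 0.23 at ZT18 (adjusted p = 0.108; by DESeq2 adjusted p = 0.01). At ZT18 the count was 2, 1 and 6 without GFP replicate 1, 2 and 3 and 3, 6 and 3 without CRE replicate 1, 2 and 3, and Cyp17a1 was past the threshold in none of these fits (adjusted p = 0.064 to 0.258). At ZT22 it was 58 and 3 without GFP replicate 1 and 2 and 13, 10 and 3 without CRE replicate 1, 2 and 3, and Cyp17a1 failed there without GFP replicate 2 (-1.26, adjusted p = 0.288), without CRE replicate 1, 2 or 3 (adjusted p = 0.111, 0.0905 and 0.131) and with the ZT22 groups alone (adjusted p = 0.573). Without the 6 libraries Cyp17a1 had adjusted p = 0.0587 at ZT18 and 0.053 at ZT22.

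The test of the difference itself, CRE against GFP among the 6 times, passed for 108 genes (402 by DESeq2). Lpin1 (adjusted p = 1.15e-08), Pptc7 (adjusted p = 1.05e-05), Cpeb2 (adjusted p = 2.58e-05), Foxo1 and Pfkfb2 (adjusted p = 5.56e-05 each) led them, and Fkbp5 passed as well (adjusted p = 0.00258). Mean Lpin1 was 1940 ± 432 CPM in GFP and 114 ± 18.2 CPM in CRE livers at ZT12, and 77.9 ± 14 and 56.4 ± 11.6 CPM at ZT22. Of the GR targets 5 of 24 passed (12 adjusted over the list alone). Nr3c1 (adjusted p = 0.589) did not. The count was 70 and 266 without GFP replicates 2 and 3 of ZT13 and 67 without CRE replicate 2 of ZT13. It was 57 among the 5 times other than ZT10 without the 6 libraries above 20% NR_046233.

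**Figure D4:**
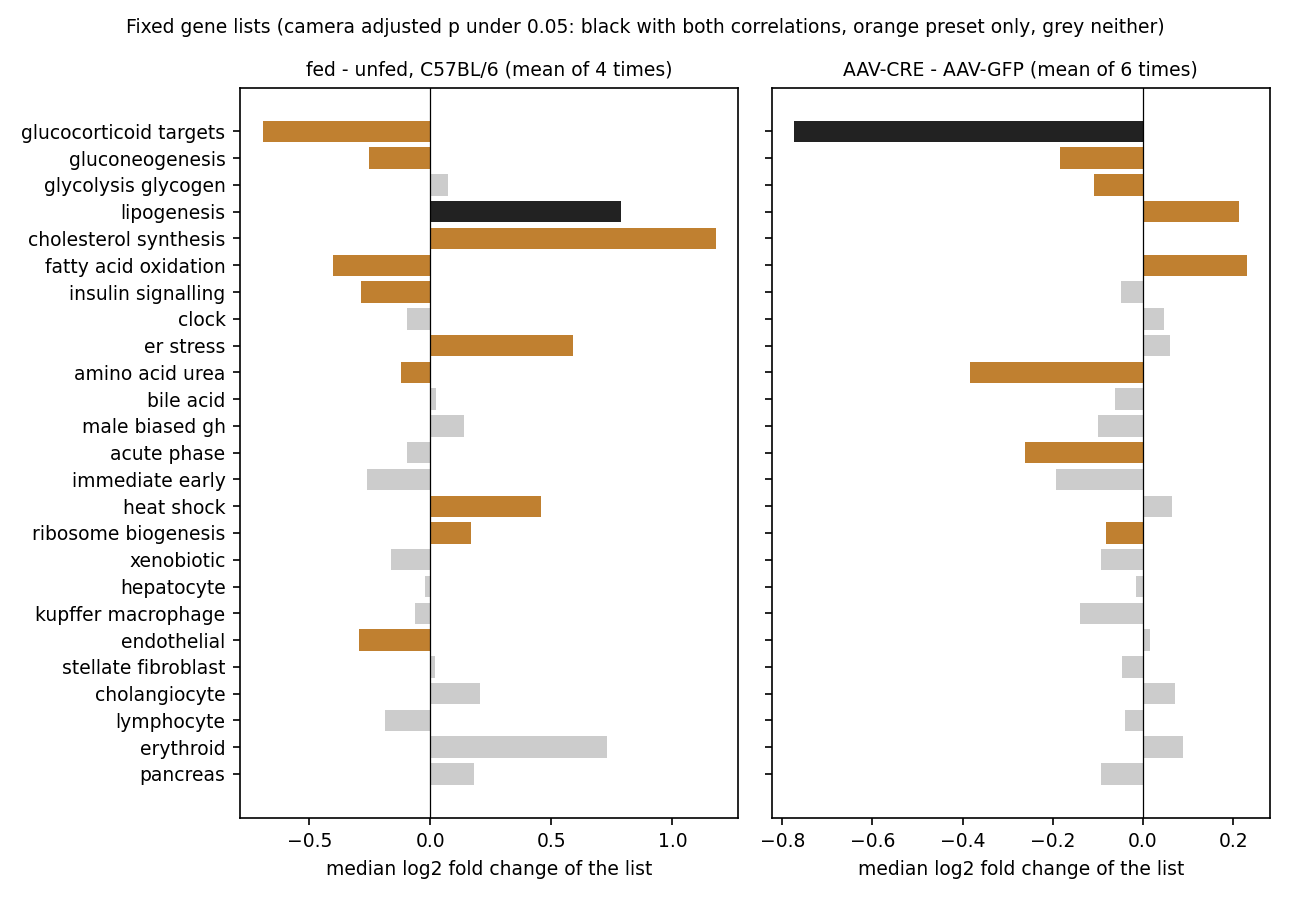
Median log2 fold change (x axis) of each fixed gene list (y axis) in fed against unfed C57BL/6 livers and in CRE against GFP livers, in black where the camera test passed with both correlations, in orange where it passed with the preset correlation only and in grey otherwise. The medians of the GR targets were -0.69 with food and -0.77 with CRE.

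The purpose of the Nr3c1fl/fl experiment, per its title, includes the response to feeding with impaired GR expression. Here fed livers at ZT13 and ZT14 were compared with unfed livers at ZT10 and ZT12, so food and hour change together. Heat shock and unfolded protein response genes rose in both viruses: Hspa1b rose by 3.15 ± 0.35 in GFP and 2.72 ± 0.32 in CRE livers, and Creld2 by 2.31 ± 0.25 and 2.91 ± 0.25. Of the heat shock genes 11 of 12 rose in each (12 and 11 adjusted over the list alone). Of the unfolded protein response genes 15 and 17 of 22 rose with 2 lower in each (18 and 19 adjusted over the list alone), and of the ribosome biogenesis genes 10 and 11 of 20 rose with 0 and 1 lower (12 and 12 adjusted over the list alone). Angptl8 rose by 2.25 ± 0.39 in GFP and 2.14 ± 0.37 in CRE livers, and Igfbp1 fell by 1.97 ± 0.52 and 3.46 ± 0.61 (interaction adjusted p = 0.728). In all, 1574 genes rose and 1305 fell with GFP, and 2093 and 1868 with CRE.

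The largest falls in fed GFP livers among genes that the rule for named genes allows were Sspn (-5.91 ± 0.77), Il31ra (-5.66 ± 0.71), Lars2 (-5.33 ± 0.69), Cntnap5b (-5.12 ± 0.60), Kcnip1 (-4.78 ± 0.72) and Jarid2 (-4.57 ± 0.65). These 6 went with the NR_046233 share, which was 21.9% ± 8.75 in the unfed and 3.99% ± 1.97 in the fed GFP livers. With that share as a covariate none of the 6 passed and 1139 genes passed in GFP livers. Leaving out the 6 libraries above 20% removes all 3 GFP libraries at ZT10 and 2 of 3 at ZT12, so the unfed GFP side is then 1 library, assumed to vary like the other groups, and ZT10 drops from both comparisons. The count was 134 in GFP and 2566 in CRE livers, and in GFP livers Hspa1b, Creld2, Angptl8 and Igfbp1 were at 2.72, 2.00, 2.96 and -2.36 (adjusted p = 0.0671, 0.0774, 0.0817 and 0.137). With the covariate Igfbp1 was at -1.24 there (adjusted p = 0.407). Whether the response differed between viruses was tested as an interaction, in which edgeR called 0 genes, with 1114 at an unadjusted p under 0.05, and DESeq2 called 22. Leaving out single libraries gave 10 genes without CRE ZT10 replicate 1, 1 and 13 without GFP ZT12 replicates 1 and 3, 2 without CRE ZT12 replicate 3, 1 without GFP ZT13 replicate 2, 3 without CRE ZT13 replicate 3, 1 without GFP ZT14 replicate 3 and 1 without CRE ZT14 replicate 1.

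Of the fixed lists, male-biased growth hormone genes leaned upward in this interaction (median 0.47, camera adjusted p = 1.62e-05; adjusted p = 0.225 with an estimated correlation), as did unfolded protein response (adjusted p = 0.000594; adjusted p = 0.621 with an estimated correlation), lipid synthesis (adjusted p = 0.00711; adjusted p = 0.621 with an estimated correlation), bile acid (adjusted p = 0.0195; adjusted p = 0.442 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.0314; adjusted p = 0.83 with an estimated correlation). Immediate early genes (adjusted p = 0.0397; adjusted p = 0.67 with an estimated correlation) and bile duct markers (adjusted p = 0.0397; adjusted p = 0.368 with an estimated correlation) leaned downward. No member of these 7 lists passed over all genes, and adjusted over the list alone 1 cholesterol synthesis and 2 immediate early genes did. By fry 0 lists passed. Without the 6 libraries above 20% NR_046233, with 1 unfed GFP library left, the lipid synthesis and bile acid lists turned downward (adjusted p = 0.963 and 0.916), and cholesterol synthesis and immediate early genes were not past the threshold (adjusted p = 0.888 and 0.0625). With the share as a covariate cholesterol synthesis, bile acid and bile duct lists were not (adjusted p = 0.226, 0.128 and 0.203). Other lists passed in these fits, both made after seeing the data and at the preset correlation. With the covariate and without the 6 libraries, amino acid and urea cycle (adjusted p = 2.07e-05 and 3.65e-05), acute phase (adjusted p = 8.56e-05 and 6.36e-05) and Kupffer cell genes (adjusted p = 0.00545 and 0.000176) leaned downward and glycolysis and glycogen genes (adjusted p = 0.0303 and 0.0119) upward. With the covariate alone fatty acid oxidation genes leaned upward (adjusted p = 8.56e-05) and GR targets downward (adjusted p = 0.024). Without the 6 libraries alone lymphoid (adjusted p = 0.0078) and red blood cell markers (adjusted p = 0.00896) leaned downward.

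Genes that responded to food in C57BL/6 livers at ZT13 or ZT14 by at least 1 log2 unit were then followed in CRE against GFP livers at ZT13 and ZT14, other mice than those that gave the set. Of 96 genes raised by food, 4 were higher and 1 lower in CRE livers (5 adjusted over the set alone), with a median of 0.16 (camera p = 0.00277; p = 0.118 with an estimated correlation). Of 82 genes lowered by food, 2 were higher and 14 lower (23 adjusted over the set alone), with a median of -0.11 (camera p = 0.00365; p = 0.243 with an estimated correlation). The share over all tested genes would give 3 higher and 3.5 lower in the raised set and 2.6 and 3 in the lowered set. The raised set was thus near that share, while the 14 lower genes of the lowered set exceeded it. At ZT12, in unfed mice, the medians were 0.21 and 0.06, so the lean of the raised set was not limited to fed livers. At ZT13 the medians were 0.35 and -0.30, and at ZT14, where the mean level of the Kupffer cell markers was lower in each CRE than in each GFP library, 0.03 and 0.01, with the mean of the lowered set at -0.05. The same sets changed with food and hour in both viruses: of the 96 genes 35 rose and 1 fell in GFP and 44 rose and 2 fell in CRE livers, and of the 82 genes 40 and 50 fell and none rose. Part of the raised set rests on fed ZT14 replicate 1, which held transcripts of other tissues: Dmbt1, Krt19, Ly6d and Muc1, picked after their values were seen, stand in the set. Sets made without it and unfed ZT18 replicate 3 held none of these 4 genes and 59 raised genes, 49 of them shared with the 96, and 76 lowered genes, 62 of them shared with the 82. Of the 59 genes 4 were higher and 2 lower in CRE livers (13 adjusted over the set alone), with a median of 0.24 (camera p = 0.001; p = 0.125 with an estimated correlation). Of the 76 genes 2 were higher and 10 lower (17 adjusted over the set alone), with a median of -0.04, and the call was lost (camera p = 0.188; p = 0.606 with an estimated correlation). Of the 59 genes 32 rose in GFP and 37 in CRE livers and none fell.

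The binding data ask where GR sits near the genes that differ between CRE and GFP livers. GR was immunoprecipitated at ZT10 from C57BL/6 livers, with an input, and from GFP and CRE livers of Nr3c1fl/fl mice, 1 sample each. The deposited lists hold 23683 peaks called against input, 18543 called against chromatin from CRE livers and 5772 of 209 bp named as concordant between replicates; which GR samples gave each list is not given in the sources used here. The concordant peaks have the coordinates of 5772 peaks of the CRE-control list, and 5772 peaks of that list overlap the input list. The overlap of the concordant list with the other lists thus follows from how it was made. Between those other lists, 24.4% of input peaks overlapped a CRE-control peak by at least 1 bp, and 31.1% the other way. Of the 1044 genes lower in CRE livers 62.9% had a concordant peak within 25 kb of the gene, against 26.2% of the other tested genes (odds ratio 4.78, 95% interval 4.20 to 5.45, two-sided Fisher exact p = 4.75e-126). Of the 1245 genes higher in CRE livers 39.3% had one, against 27.7% of the others (odds ratio 1.69, 1.5 to 1.9, p = 4.34e-17 by the same exact test). With mean expression in a logistic model over 15712 genes the odds ratios were 3.89 and 1.22. With the list called against input the lower and higher genes were closer to each other: 85.1% and 81.4% had a peak, against 60.4% of the other genes in each case (odds ratios 3.73 and 2.88). Genes are not independent units in these tests, and each list is a single set of peaks without replicate values.

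Of 22 fixed genes 18 had a concordant peak within 25 kb, all but Egr1, Fasn, Hspa5 and Pdk4. In mm10 coordinates Fkbp5, at 28398753 to 28486149 on chromosome 17, held 4 peaks, and Tat, at 109986078 to 109999804 on chromosome 8, had 4 within 25 kb with 1 of them inside. Tsc22d3, at 140539528 to 140600522 on chromosome X, had 8, of which 5 were inside. Nr3c1, at 39410545 to 39519421 on chromosome 18, held 1. Exons and introns were not used here, so a peak is placed only inside or outside a gene.

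**Figure D5:**
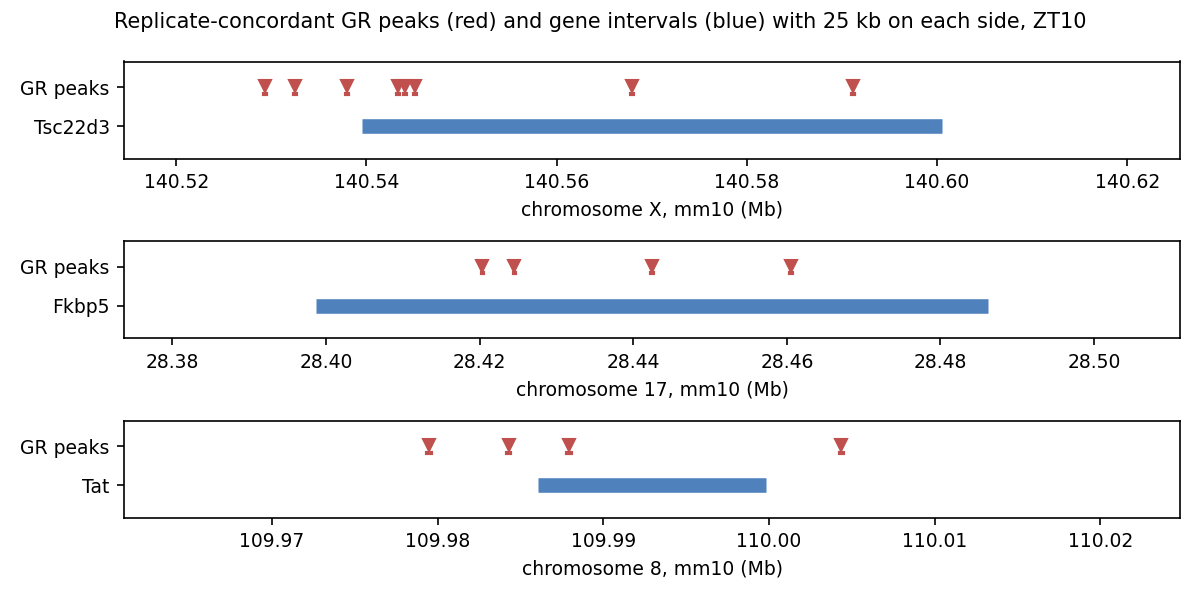
Maps of Tsc22d3, Fkbp5 and Tat with 25 kb on each side (x axis, mm10 position), with the gene interval as a bar and concordant GR peaks at ZT10 as marks. Tsc22d3 has 8 peaks in its window, Fkbp5 has 4 and Tat has 4.

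In rat hepatocytes the question is how dexamethasone and insulin act alone and together. The deposited rat table gives RefSeq identifiers without gene names, so groups of genes were not described. Dexamethasone raised 612 and lowered 527 of 10843 transcripts, insulin raised 938 and lowered 853, and both together raised 1743 and lowered 1689 against the control. NM_001013181 rose by 3.17 ± 0.08 with dexamethasone (adjusted p = 4.94e-18), from 7.04 ± 0.66 to 63.9 ± 3.12 CPM (mean ± SD, n = 3), and NM_001271205 fell by 1.68 ± 0.06. NM_013098 fell by 3.06 ± 0.15 with insulin, from 29.6 ± 3.31 to 3.55 ± 0.61 CPM, and fell by 2.97 ± 0.14 with both. The insulin count was 1167 without insulin replicate C.

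On top of insulin, dexamethasone raised 952 and lowered 1193 transcripts (1293 in all without insulin replicate B, 1383 without combined replicate C), and on top of dexamethasone, insulin raised 1217 and lowered 1289 (1622 in all without dexamethasone replicate A). The interaction, a departure from the sum of the single effects on the log2 scale, passed for 72 transcripts, 9 above and 63 below the sum. NM_001014071 led it at -1.24 ± 0.05 (adjusted p = 1.41e-12): its mean was 188 ± 6.11 CPM in the control, 436 ± 11 with insulin, 1100 ± 33.2 with dexamethasone and 1080 ± 17.6 with both. That count was 45 and 47 without control replicates A and B, and 109 and 45 without insulin replicates A and C.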

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

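Tests of depth, spread and Nr3c1 loss, of the 6 genes against NR_046233 and of endothelial against Kupffer cell markers were chosen only after the result was seen, as were all fits with the NR_046233 share or without libraries high in it. The difference of the response to food among hours passed for 1194 genes, that of CRE against GFP among times for 108 genes, and the interaction of dexamethasone and insulin for 72 transcripts, each a tested difference between groups. NR_046233, a row outside all comparisons, held 28.5% of counts in CRE ZT10 replicate 1.

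With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 162 and 9 at ZT13, 831 and 1 at ZT14, 3897 and 1 at ZT18 and 2984 and 28 at ZT22 for food, where 1 split, the real one, was as large. For CRE against GFP they were 109 and 1 at ZT10, 589 and 6 at ZT12, 792 and 232 at ZT13, 247 and 15 at ZT14, 16 and 0 at ZT18 and 23 and 36 at ZT22, where 2 splits were as large. In hepatocytes they were 1139, 1791, 3432, 2145 and 2506 against 0 in each case, for dexamethasone, insulin, both against control, dexamethasone with insulin and insulin with dexamethasone.

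Where 100 splits were drawn, only the real one reached its count in 7 comparisons, which argues against chance for them without excluding it. The real count and the highest of the other splits were 5215 and 984 for food averaged over hours, 1194 and 821 for food by hour and 6260 and 2015 for unfed time. They were 2289 and 121 for CRE averaged over times, 108 and 94 for CRE by time, 2879 and 287 for food in GFP and 3961 and 944 for food in CRE livers. The margin was small for CRE by time. The other splits mix the groups compared, so they carry part of the differences between them. For both other interactions the splits leave chance open. The count of 0 for virus by food is one that any of the 100 splits reaches (highest 148). For dexamethasone and insulin 6 of 100 reached 72 and the highest was 1790: such large counts point to a structure of the samples, since a split that mixes hepatocyte treatments carries their own effects.

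More genes differed between CRE and GFP at ZT12, ZT13 and ZT14 than at ZT18 and ZT22, and a contrast of the late with the early times passed for 237 genes. The listed GR targets had a median of -1.30 early and -0.19 late, and 21 of 24 had a higher log2 fold change late than early. The median difference was 0.96 (mean difference 0.95, permutation p = 0.0259 over 3200000 rearrangements). The permutation exchanged GFP and CRE libraries within each time. Its null is therefore no CRE effect at any time, and it gives no exact test of equal effects early and late. For these targets the smaller fold changes themselves argue against lower depth or wider spread alone as the cause. Median tested totals were 24.8 M late and 29.4 M early, 84.2% of the early value, a ratio that alone decided nothing: it lay between the bounds first set for depth, and the fold changes were added to that criterion after the ratio was known. A smaller loss of Nr3c1 late stays open, since its log2 fold change differed by 0.23 ± 0.13 (95% interval -0.02 to 0.48). Nr3c1 ran from 198 to 323 CPM in the early GFP libraries and from 147 to 190 CPM in the late ones. In CRE libraries it ran from 102.5 to 201 CPM early and from 110 to 137 CPM late. The narrower gap thus goes with lower levels in GFP livers, not with higher levels in CRE livers. A difference by hour or by time since feeding may also account for the smaller number of genes late. Hour and time since feeding were not tested apart. They change together among the livers at ZT13, ZT14, ZT18 and ZT22, which were all fed.

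The 6 genes with the largest falls in fed GFP livers, among those that the rule for named genes allows, followed the NR_046233 share within groups. Their r was 0.911 to 0.978 and Spearman's rho 0.868 to 0.975 (permutation p = 1e-04 for each, adjusted 1e-04, the smallest that the permutations can give, over 6 relations). Without the 2 farthest libraries r was 0.859 to 0.969. With the share as a covariate 0 of the 6 passed edgeR's test, with Lars2 at -0.46 and Kcnip1 at 0.42. Leftover RNA of the kind counted at NR_046233 is a candidate explanation. A response to food stays open: in C57BL/6 livers at ZT13 and ZT14 their median was -0.86, between the bounds set in advance, and none passed there.

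Endothelial markers were lower in fed C57BL/6 livers by 0.31 log2 units as a mean of 10 genes (-0.31, exact permutation p = 3.75e-05, adjusted p = 0.000262 over 7 comparisons), at 4 of 4 hours. Kupffer cell markers (-0.02, p = 0.886 by the same exact test) and stellate markers (0.14, exact p = 0.0857) moved apart from them: the endothelial list lay below the Kupffer list by -0.29 (exact p = 0.00564, adjusted p = 0.0132) and the stellate list by -0.44 (exact p = 0.000375, adjusted p = 0.00131), which argues against a lower share of all cells other than hepatocytes, and against scaling of the libraries as the whole cause, since a factor per library moves both lists alike. By hour, Kupffer cell markers were lower in fed livers at 3 of 4 hours and stellate markers at 0 of 4. At ZT14 Kupffer cell markers were higher, at 3.65 to 4.28 in fed and 3.45 to 3.48 in unfed libraries (mean log2 level). The highest of these, fed replicate 1, held transcripts of other tissues. The comparison with Kupffer cells therefore leans on that hour. A change of endothelial cells or of their transcripts with food may remain, as a hypothesis found and tested on the same data.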

How the results depend on the processing

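Fits with the NR_046233 share, without libraries high in it or without 2 libraries with other tissues' transcripts, sets made without those 2, and halved counts, were chosen after seeing the data. Of 148 results for single named genes 116 kept direction and side of the threshold in all settings run and 32 did not. RLE factors, no filter and halved counts moved no count of genes by over 1.5 times. The cause was not tested for any change below, and in some of these settings fewer libraries or groups enter the fit.

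DESeq2 called 350 genes for food at ZT13 and 1871 for food by hour, and for CRE against GFP 197 at ZT10, 417 at ZT14, 80 at ZT18, 92 at ZT22 and 402 by time, with 22 for virus by food. With the 2 groups alone the counts were 95, 1318 and 1752 for food at ZT13, ZT14 and ZT22 and 55, 65 and 0 for CRE at ZT13, ZT18 and ZT22 (edgeR, fewer samples to estimate the spread; the full fit called 23 at ZT22 and DESeq2 92). Without the 2 libraries with other tissues' transcripts, food at ZT14 gave 444. With the covariate CRE gave 65 at ZT10 and 229 at ZT12, and food in GFP livers 1139. Without the 6 libraries over 20% NR_046233, which leaves no GFP library at ZT10 and 1 at ZT12, CRE gave 105 at ZT12, 10 at ZT22, 1372 as a mean and 57 by time, and food 134 in GFP and 2566 in CRE livers.

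The sets of food genes had p = 0.118 (raised) and 0.243 (lowered) with an estimated correlation, and the lowered set p = 0.0529 by fry, 0.315 with any fold and 0.188 when made without the 2 libraries with other tissues' transcripts. With an estimated correlation 1 list passed for food, 1 for CRE and 0 for virus by food, and by fry 0 for the last, where camera with a preset correlation passed 7. Overlap by at least 50% of a peak held for 71.4% of concordant peaks in the input list, 18.1% of input peaks in the CRE-control list and 22.2% the other way.

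Directions turned for Il31ra (0.56), Kcnip1 (0.48) and Jarid2 (0.17) in fed GFP livers without the 6 libraries, against 1 unfed library, and for Kcnip1 (0.42) and Jarid2 (0.088) with the covariate; for Tsc22d3 with food without fed ZT22 replicate 2 (-0.05, with a range of -0.052 to 0.122 over single omissions); and for lists, of which lipid synthesis and bile acids in virus by food had passed and the others had not. As adjusted p these were pancreas with food by fry (0.979), bile acids (0.845) and pancreas (0.692) for CRE without the 6 libraries, and for virus by food insulin signalling by fry (0.957), clock (0.956), heat shock (0.776), ribosome biogenesis (0.202) and pancreas (0.962) with the covariate, and lipid synthesis (0.963), bile acids (0.916), heat shock (0.372) and xenobiotic genes (0.662) without the 6 libraries.

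Leaving out 1 library at a time, the counts ranged, for food, from 40 to 434 at ZT13, 389 to 655 at ZT14, 2530 to 3993 at ZT18, 2271 to 2725 at ZT22, 4820 to 5318 as a mean, 853 to 1612 by hour and 5216 to 6531 for unfed time. For CRE they ranged from 43 to 78 at ZT10, 267 to 483 at ZT12, 375 to 1343 at ZT13, 74 to 222 at ZT14, 1 to 6 at ZT18, 3 to 58 at ZT22, 2061 to 2493 as a mean and 67 to 266 by time. Food in GFP livers gave 2355 to 2822, in CRE livers 3157 to 3888 and their interaction 0 to 13. In hepatocytes the ranges were 856 to 982 (dexamethasone), 1167 to 1633 (insulin), 2589 to 3316 (both), 1293 to 2414 and 1622 to 2363 (each on top of the other) and 45 to 109 (interaction). For the sets, p ranged from 3.88e-05 to 0.0369 (raised) and 0.000192 to 0.05 (lowered).

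Same-numbered mouse libraries deviated together little (mean r 0.011 and 0.006 in the 2 experiments, against -0.006 and -0.003 for other numbers). In these, 13 of 27 and 15 of 36 libraries were closest to their own number, and single same-numbered pairs reached r = 0.261 and 0.364. The numbers were thus not treated as pairs, though a weak pairing is not excluded. With the replicate block the counts were 183 for food at ZT13, 5254 for food as a mean and 2297 for CRE as a mean, none moved by over 1.5 times. The block was not run for hepatocytes, whose letters the labels do not explain, nor were the peaks split by score, since the lists hold no scores.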

Other observations

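The lists below were fixed before the data were examined, while the single libraries and the genes chosen by size were picked only after their values were seen. In CRE livers acute phase genes were lower in 5 of 19 cases with none higher (7 adjusted over the list alone; camera adjusted p = 0.000323; adjusted p = 0.538 with an estimated correlation). Lcn2, which carries siderophores, fell by 2.82 ± 0.39 (edgeR, mean of 6 times), and Hp, the haptoglobin gene, fell by 0.76 ± 0.10. Ribosome biogenesis genes were lower in 3 of 20 cases (4 adjusted over the list alone; adjusted p = 0.0143; adjusted p = 0.597 with an estimated correlation). Of the hepatocyte markers Apoa1 was at -0.66 ± 0.06. Clock genes went both ways, 5 higher and 4 lower of 18 (12 adjusted over the list alone; adjusted p = 0.467), with Nr1d1 at 0.68 ± 0.12, Dbp at 0.54 ± 0.09 and Per1 at -0.67 ± 0.10. Of the male-biased growth hormone genes 2 were higher and 2 lower of 15 (4 adjusted over the list alone; adjusted p = 0.423), with Serpina1e at -1.26 ± 0.24, Mup20 at -0.99 ± 0.17 and Cyp8b1 at 0.38 ± 0.10.

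Also in CRE livers, the cytochrome P450 genes Cyp2b9 and Cyp2a4 were higher by 5.68 ± 0.95 and 3.26 ± 0.60, with a wide spread within CRE groups: at ZT22 Cyp2b9 was at 28.4 ± 45.1 CPM in CRE and 1.22 ± 2.04 CPM in GFP livers. Eif4ebp3 fell by 2.78 ± 0.13 and Cyp17a1 fell by 3.03 ± 0.23. At ZT22 Mcm5 (2.30 ± 0.33), Mcm6 (1.47 ± 0.28) and Pole (1.26 ± 0.20) were called higher in CRE livers, with Mcm5 at 10.9 ± 2.42 against 2.24 ± 0.91 CPM. These are 3 of the 23 genes called at ZT22, where another split of the libraries called 36 and the ZT22 groups alone called 0 (DESeq2 92). With those groups alone Mcm5, Mcm6 and Pole had adjusted p = 0.0969, 0.575 and 0.407. Mcm6 also failed without the 6 libraries over 20% NR_046233 (adjusted p = 0.053) and without GFP replicate 1 or 2 or CRE replicate 1 or 3 (adjusted p = 0.0592, 0.0928, 0.0778 and 0.0741) and Pole without GFP replicate 2 (adjusted p = 0.0836).

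The other lists gave no call by camera. In CRE livers these were, as higher and lower members, insulin signalling with 0 and 3 of 14 (adjusted p = 0.287), unfolded protein response with 1 and 1 of 22 (adjusted p = 0.754; median 0.06, mean -0.05), bile acids with 1 and 2 of 12 (adjusted p = 0.467), immediate early with 0 and 1 of 12 (adjusted p = 0.165), heat shock with 0 and 1 of 12 (adjusted p = 0.463) and xenobiotic metabolism with 2 and 4 of 16 (adjusted p = 0.5). With food they were bile acids with 1 and 5 of 12 (adjusted p = 0.541; median 0.02, mean -0.05 and a downward test), male-biased growth hormone genes with 3 and 2 of 15 (adjusted p = 0.475), acute phase with 2 and 4 of 18 (adjusted p = 0.583), xenobiotic metabolism with 5 and 8 of 16 (adjusted p = 0.236) and the markers of hepatocytes (adjusted p = 0.87; median -0.02, mean 0.00), stellate cells with 3 and 0 of 11 (adjusted p = 0.741), bile duct cells with 1 and 1 of 6 (adjusted p = 0.87; median 0.21 and a downward test), lymphoid cells with 1 and 0 of 7 (adjusted p = 0.983; median -0.19 and an upward test), red blood cells with 1 and 0 of 5 (adjusted p = 0.361) and pancreas with 0 of 3 (adjusted p = 0.997). The cholesterol list in CRE livers had a median of 0.00, a mean of -0.00 and an upward test. Of the neutrophil markers 1 was measured with food and 2 with CRE, of the fat cell markers 2 in each and of the mitochondrial transcripts 0, too few for a test.

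Single libraries held transcripts of other tissues. Unfed ZT18 replicate 3 of the C57BL/6 livers had the pancreatic genes Ctrb1 at 89.9 CPM, Pnlip at 59.3 CPM and Cpa1 at 33.5 CPM, where the next highest library had 16, 0.348 and 0.261 CPM. Fed ZT14 replicate 1 had Dmbt1 at 823 CPM and Krt19 at 60 CPM, against 13.4 and 2.71 CPM in the next highest. In GFP ZT22 replicate 3 Wt1 was at 20.3 CPM, Col3a1 at 180 CPM and Slit3 at 53.4 CPM, against 3.2, 41.9 and 4.28 CPM.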
